A study of Ovis aries with 30 samples.

How the data were processed

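Whole blood of 15 lactating crossbred ewes was profiled on 1-colour arrays, giving 30 arrays in 4 groups. Per the labels, 10 ewes belonged to the zinc arm and 5 to the control arm, and each arm has arrays of day 0 and of day 40. The days are read from T0 and T40 in the sample titles and the 40-day treatment period, since the design text mentions blood collection only after treatment. All ewes were acclimatised for 4 weeks on a basal diet supplying 79 mg of zinc per animal per day. The control arm stayed on that diet and the zinc arm then received 212 mg per animal per day. Per the labels' protocols, blood was stabilised in PAXgene tubes, and RNA was amplified and labelled with Cy3 by the Agilent 1-colour protocol. The scanner, the feature extraction and the normalization software are not given in the sources used here.

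The deposited values are intensities, the brightness of each array feature on a linear scale, for 45220 numbered features. The scale was read from the values, which lie far above any log scale and are never negative, and no centring was seen. Within each arm the sorted intensities were nearly the same on every array. The 10000th highest value lay between 516.6 and 520.2 on the 20 zinc arrays and between 585 and 589.8 on the 10 control arrays. Such values arise when quantile normalization is run in each arm apart, a step that no label records. Levels of the 2 arms are therefore not on a common scale, and each comparison between arms is given with its count after a common scaling. Whether any background was subtracted is not known.

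Many cells of the table are empty, and their meaning is not stated. In all, 1193 features were empty on every array, 44027 had a value on at least 1 array, and 22526 had a value on all 30. Empty cells made up 38% of the dimmest 25% of features and 0.675% of the brightest, so they are not missing at random. Since 50.2% of features had a gap, the rule set for that case kept the 34809 features with values on at least 3 arrays of each of the 4 groups, 12283 of them with a gap. No filter on brightness was applied. Array depth has no count here, and the number of arrays limits the precision.

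The log2 intensity, with no pseudocount, was fitted with limma 3.58.1 in R 4.3.3. The model held 1 mean for each of the 4 groups, so that all 30 arrays shared an estimate of the spread. Its 5 contrasts were the change over time in each arm, the difference between the arms on each day, and the difference between the 2 changes. Adjusted p-values are Benjamini-Hochberg values within a contrast, with a threshold of 0.05. The model, the threshold and most alternatives were chosen before the data were examined.

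The labels do not state that equal numbers at day 0 and day 40 are the same ewe, although they count 15 ewes for 30 arrays. Arrays of equal number deviated together from their group means over 16216 features. The correlation of these deviations was between 0.263 and 0.783 in all 15 pairs, and 29 of 30 arrays correlated best with their own number. The numbers were taken to pair the arrays. A fit with the ewe as a block, made on the differences between days within a ewe for 34325 features, is given beside each result it changed. It needed at least 2 pairs in each arm.

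The files do not pair the feature numbers with genes, and the reference table holds no such numbers. The gene lists set beforehand, for zinc handling, other pathways and blood cell markers, and the tests on them were therefore not run. Named genes were to be those with the largest rise and fall past the threshold. With no gene names, the rule was kept for features of the zinc arm's change over time, limited to the 2 largest rises and the 2 largest falls.

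The procedure was tested on simulated data with 200 features changed in the zinc arm or the control arm at day 40. For the zinc arm's change over time, the fit over 34809 features called 52.2% of features changed by 0.5 on the log2 scale, 79.1% of those changed by 1 and 97% of those changed by 2. In the control arm these shares were 26.9%, 70.1% and 92.4%. For the difference in time change with the change placed in the zinc arm, they were 1.49%, 46.3% and 84.8%, or 11.9%, 55.2% and 84.8% with the ewe as a block. Calls among unchanged features numbered at most 1 without the block and between 7 and 15 with it. The simulated noise was independent between features and held no differences between whole arrays. Empty cells were placed as in the data, whatever the simulated level. The shares and false calls on the real arrays may therefore differ.

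Alternatives covered the block, the scaling between arrays, brightness filters, the variance model, array weights, a fit to the compared groups alone, a minimum change of 1.5-fold, and leaving out each array in turn. Others were added after the data were examined. These used features with values on all arrays, a quantile normalization over all 30 arrays in which empty cells took the lowest ranks, called the common scale here, and terms for the number of empty cells. They also included parts of the zinc arm and the removal from each array of a running median over 101 neighbouring feature numbers. Arrays were sorted into 3 classes at the widest gaps in their number of empty cells: 4 arrays with 2524 to 2706, 14 with 5100 to 8152 and 12 with 10239 to 12983.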

Results

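Zinc is an essential trace metal, and the series asked how blood transcripts of lactating ewes respond to extra zinc in the diet. Blood was profiled at day 0 and day 40 in 10 ewes moved to 212 mg of zinc per animal per day and in 5 ewes kept on 79 mg. The features of the array carry numbers only, which the files do not pair with genes, so no gene, pathway or cell type is named. Changes are given as log2 differences of intensity.

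The arrays differed in how many features had no value. Empty cells numbered 4902 ± 2110 (SD, n = 10) in the zinc arm at day 0 and 11370 ± 1271 (SD, n = 10) at day 40. In the control arm they numbered 7407 ± 2729 (SD, n = 5) and 7178 ± 2158 (SD, n = 5). The 4 arrays with the fewest empty cells were day 0 arrays of zinc ewes 1 to 4, and 9 of the 10 zinc arrays at day 40 fell in the class with the most. The median intensity of features with values on all arrays lay between 358.4 and 365.3 on the zinc arrays and between 409.3 and 411.4 on the control arrays. In a principal component analysis of 16216 features, the second component, with 12% of the variance, separated the day 0 arrays of zinc ewes 5 to 10, at -33.14 to -13.33, from the other arrays, at -3.953 to 20.01.

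**Figure D1:**
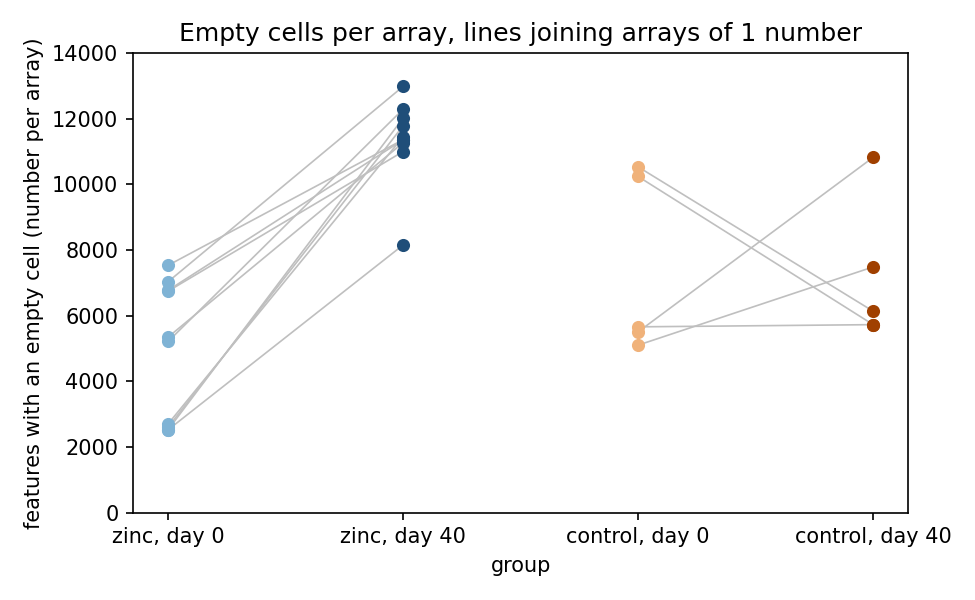
Number of features with an empty cell on each array (vertical axis, number per array) by group, with lines joining the 2 arrays of equal number. The zinc arrays lie between 2524 and 7534 at day 0 and between 8152 and 12983 at day 40.

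**Figure D2:**
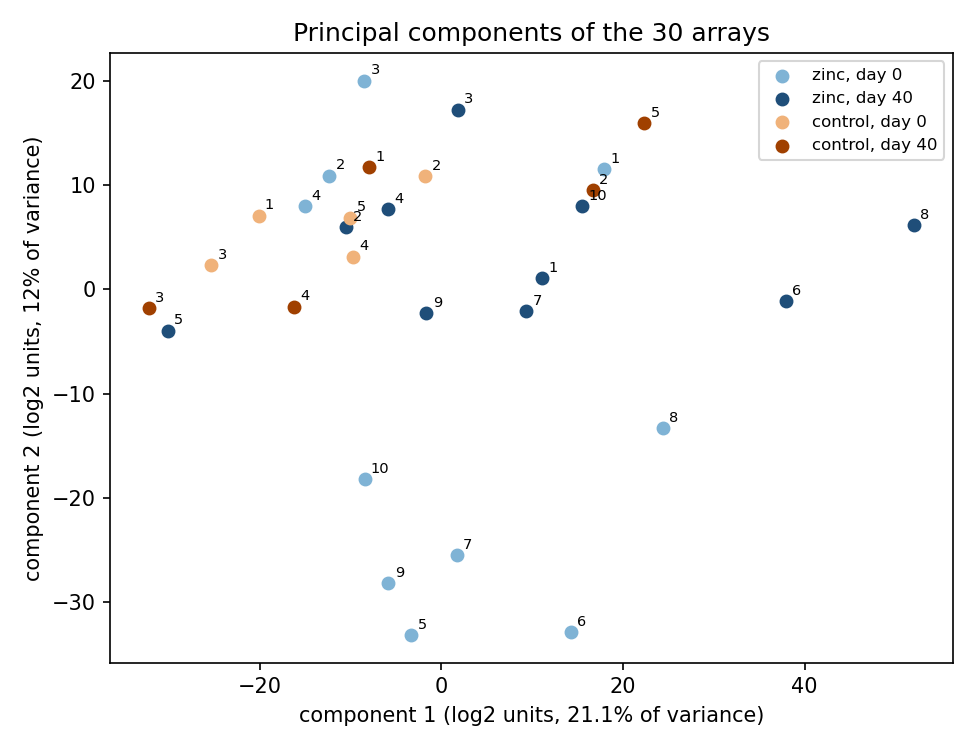
Principal components 1 and 2 of the 30 arrays (axes in log2 units, with the percent of variance), each point an array with its ewe number, coloured by group. The day 0 arrays of zinc ewes 5 to 10 lie lowest on component 2, at -33.14 to -13.33.

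The first comparison asked what changed in the zinc arm between day 0 and day 40. Of 34809 features, 1607 changed, 1148 upward and 459 downward (limma, adjusted p under 0.05, n = 10 and 10). The median size of these changes was 0.43 on the log2 scale, 429 of them reached 1.5-fold and 77 reached 2-fold. Calls were spread over the brightness range: the dimmest 25% of features held 142 rises and 74 falls, and the brightest held 278 and 182. With the ewe as a block the count was 4457, with 2700 rises and 1757 falls, and 1485 of the 1607 features were called in the same direction in both fits. The blocked split moved with the scale and with the set of features. It was 3432 up and 1689 down on the common scale described below. Once a running median over neighbouring feature numbers was removed, it was 2100 up and 2222 down, with falls the majority. On features with values on all arrays it was 2818 up and 2004 down. After these were quantile normalized together it was 2595 up and 2219 down. Limma's quantile normalization, which ignores empty cells, gave 13338 calls, 175 up and 13163 down, with the median of all features at -0.299. When empty cells were ranked lowest instead, on the common scale, 2391 features were called, 1922 up and 469 down, 1530 of them among the 1607. The median change on that scale was 0.0593. With the running median removed and no block, 1437 were called, 856 up and 581 down. The count was 1057 without the day 0 array of ewe 9 and 1068 without the day 40 array of ewe 10. With zinc ewes 1 to 4 alone 262 features were called, and with ewes 5 to 10 alone 3248, or 217 and 6823 with the block. These sets differ in size, so the counts also differ in precision. The changes of the sets correlated at r = 0.155 across features with values on all arrays. The 1607 calls therefore need not be shared by all 10 ewes.

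The largest rises in the zinc arm were those of features 19829 and 11678. Feature 19829 went from 2.81 ± 1.06 (SD, n = 10) to 4.57 ± 0.27 (SD, n = 7) on the log2 scale. This rise of 1.76 (SE 0.35, limma adjusted p = 0.00649) was seen in 7 of 7 ewes with both values. The day 0 intensities of ewes 2, 3 and 4 were 2.787, 2.77 and 2.792, close to the lowest value on those arrays, 2.595 to 2.598, so the size of the rise is uncertain. In the control arm the feature changed by 0.27 (SE 0.48, limma adjusted p = 1). Feature 11678 went from 3.26 ± 0.63 (SD, n = 8) to 4.93 ± 0.21 (SD, n = 6), a rise of 1.68 (SE 0.26, limma adjusted p = 0.002) seen in 4 of 4 ewes. It was at 5.02 ± 0.27 (SD, n = 3) in the control arm at day 0 and 4.91 ± 0.61 (SD, n = 4) at day 40.

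The largest falls were those of features 36109 and 41820. Feature 36109 went from 5.19 ± 0.71 (SD, n = 9) to 3.58 ± 0.90 (SD, n = 6), a change of -1.61 (SE 0.42, limma adjusted p = 0.0303) with 6 of 6 ewes lower. In the control arm it was higher at day 40 in 5 of 5 ewes, by 1.28 (SE 0.51, limma adjusted p = 0.906). Feature 41820 went from 6.08 ± 0.44 (SD, n = 10) to 4.62 ± 0.68 (SD, n = 8), a change of -1.46 (SE 0.29, limma adjusted p = 0.00501) with 8 of 8 ewes lower. In the control arm it was higher in 5 of 5 ewes, by 0.74 (SE 0.39, limma adjusted p = 0.924). All 4 features were dim and had empty cells, most often on zinc arrays of day 40. Their means at day 40 therefore leave out arrays on which the level was not given. Empty cells were most frequent among dim features, so these gaps may raise the day 40 means. That would favour both rises and the counts of ewes with a rise, and make the falls look smaller. The call on feature 36109 was lost without 1 of 5 arrays, which were the day 0 array of ewe 9 and the day 40 arrays of ewes 2, 3, 4 and 10, with adjusted p-values between 0.0548 and 0.0738. In zinc ewes 1 to 4 alone features 36109 and 41820 changed by -2.47 and -2.14, and in ewes 5 to 10 alone by -0.95 and -1.04, and neither passed the threshold in either set.

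**Figure D3:**
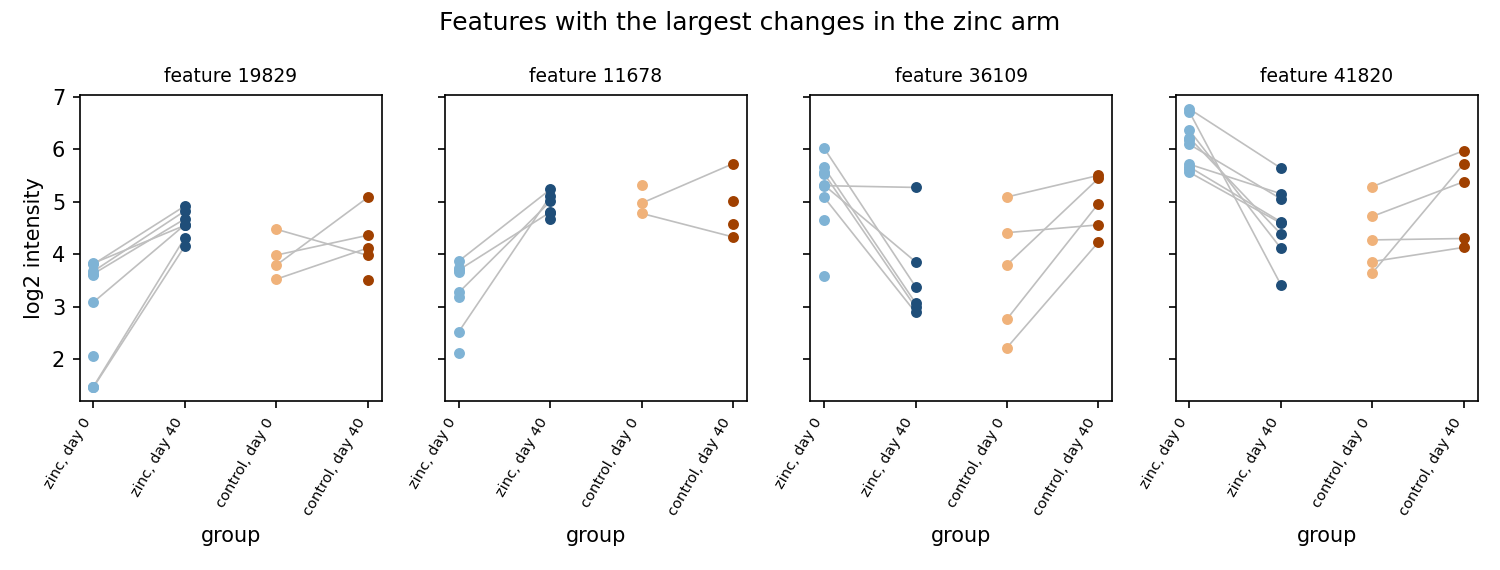
Log2 intensity (vertical axis) of the 4 features with the largest changes in the zinc arm, each point an array and each line an ewe measured on both days. In zinc ewes with both values, features 19829 and 11678 rose in 7 of 7 and 4 of 4, and features 36109 and 41820 fell in 6 of 6 and 8 of 8. Ewes with an empty cell on either day are not counted, which may favour the rises.

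The second comparison asked what changed over the same 40 days without extra zinc. No feature passed the threshold in the control arm (limma, 0 of 34809, n = 5 and 5). The lowest adjusted p was 0.089, and 1853 features had an unadjusted p under 0.05. The log2 changes of the central 90% of features ran from -0.411 to 0.457, against -0.367 to 0.547 in the zinc arm. With the ewe as a block 2 features were called, 1 up and 1 down, and with the ewe as a random effect 51 were. The random effect fit gives only approximate standard errors for features with a gap. Leaving out 1 array gave between 0 and 22 calls, the most without the day 0 array of ewe 5.

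A call in 1 arm and not in the other does not show that the arms differed, so the changes themselves were compared. No feature's change over time differed between the arms (limma, 0 of 34809), the lowest adjusted p was 0.0687, and 2864 features had an unadjusted p under 0.05. With the ewe as a block 74 of 34325 features differed, 28 higher and 46 lower in the zinc arm. All 74 had opposite signs in the 2 arms, and 63 of them were also called in the zinc arm with the block. Selection for a large difference between the arms favours both counts, so they do not show a reversal by themselves. Feature 36109 was among them, at a difference of -3.19 (adjusted p = 0.0494 in limma with the block). Features 41820, 11678 and 19829 were not, with adjusted p-values of 0.0645, 0.277 and 0.307 in the same fit. The blocked count was 1 without control ewe 2 and 163 without zinc ewe 1. With zinc ewes 1 to 4 alone the blocked count was 0, and with ewes 5 to 10 alone it was 2471, though these sets differ in size. With the ewe as a random effect, a fit that is approximate for features with a gap, 638 features differed. Without the block, other settings also gave calls: 20 features on the common scale (14 higher, 6 lower), 35 with array weights and, on features with values on all arrays, 179 with array class as a block and 1069 with the number of empty cells as a covariate. The fit with array class rests on ewes 5 to 10 for the zinc arm at day 0, since no other group holds the class of ewes 1 to 4. Limma's quantile normalization gave 1931, 11 higher and 1920 lower.

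Across features, the 2 arms' changes over time correlated at r = 0.0947 (Pearson) and rho = 0.159 (Spearman). The Pearson value was 0.161 on features with values on all arrays, 0.0476 on the common scale and 0.156 with both. Features are not independent replicates. When arms were relabelled at random within each day, 90 of 100 draws gave an r as high, with a median of 0.193. When whole ewes were relabelled, all 99 draws gave a higher r, from 0.197 to 0.446. Relabelling spreads zinc ewes 5 to 10, whose changes correlated with each other at a median of 0.48, over both arms, which by itself raises r. The draws therefore do not tell why the arms' changes were less alike. Of the 4457 features called in the zinc arm with the block, 63% had the same sign in the control arm, against 57.5% of all features.

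The third comparison set the arms side by side after treatment. On the deposited values 510 features differed at day 40, 14 higher and 496 lower in the zinc arm (limma, n = 10 and 5). The median of all features was at -0.13, the offset between the arms. On the common scale, where that median was 0.0587, 10 features differed, all 10 higher in the zinc arm, and 6 of them were among the 510. With zinc ewes 5 to 10 alone 368 differed on that scale, 362 higher and 6 lower, against 1109 on the deposited values, 257 higher and 852 lower. With each array's median set equal 2 differed. On features with values on all arrays, quantile normalized together, 0 differed with all zinc ewes. The deposited count ran from 7 without the control array of ewe 1 to 1000 without that of ewe 5.

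The same contrast at day 0, before any extra zinc, gave 4748 features, 240 higher and 4508 lower in the zinc arm, with a median of all features at -0.135 (limma, n = 10 and 5). On the common scale, with a median of 0.00317, 956 features differed, 474 higher and 482 lower, and 682 of them were among the 4748. With each array's median set equal 1225 differed, 711 higher and 514 lower. On these 3 scales more features differed at day 0 than at day 40, but limma's quantile normalization turned this order, with 352 features at day 0, 260 higher and 92 lower, and 3707 at day 40, 7 higher and 3700 lower. Among arrays of the middle class of empty cells alone, on the common scale, 2308 of 29573 features differed at day 0 between 6 zinc and 3 control arrays. These 6 are the day 0 arrays of zinc ewes 5 to 10, which stood apart on the second principal component.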

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

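For the change in the zinc arm, the tests of the day 0 arrays and of zinc supplementation were chosen after their results were seen, as were those of separate normalization, the common scale, the ewe sets, the classes of empty cells, array class as a block and the change added to control arrays. The tests of array class in the control arm, of 5 ewes, of the day 0 arrays in the comparison between arms and of the other splits were written before their values were seen.

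A sample stood apart from its group in 2 of 23 groups of values, where chance gives about 1 in 20. The day 40 array of zinc ewe 4 had 8152 empty cells, against 10999 on the nearest other array of its group. The day 0 array of zinc ewe 3 had a median intensity of 358.4 over features with values on all arrays, against 362.8 for the nearest. With the ewe as a block, the change over time differed between the arms in 74 features.

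For the change in the zinc arm, no other of 100 splits of the 20 zinc arrays gave as many calls as the real 1607 (1 of 100, highest other 20). Swapping days within ewes did not either (1 of 100, highest other 281, or 4457 against 2276 with the block). This argues against chance but does not exclude it. The swaps treat ewes as independent, while changes of 2 ewes within ewes 5 to 10 correlated at a median of 0.48. A shift shared by the high class of arrays as the whole cause is argued against: high minus middle class in the control arm (3 against 7 arrays, 0 of 22526 features called) correlated with the zinc arm's change at r = -0.0599, or -0.0807 to -0.0296 without 1 array, under the bound of 0.1 set beforehand, while that change, reduced for its noise and added to other sets of 3 control arrays, gave a computed r of 0.115 to 0.454 in 100 draws. The ewe was not a block in this class contrast, so differences between control ewes enter it. With array class as a block on features with values on all arrays 2044 were called, against 1596 without it. The low class held only day 0 arrays of zinc ewes 1 to 4, so that fit sets them aside and compares day 40 with ewes 5 to 10 at day 0. Its higher count therefore decides nothing about a class effect. The control arm has no array of the low class, so that class also stays outside the test of r. A state of the day 0 arrays of ewes 5 to 10 is a candidate explanation that was seen before it was tested, so its values do not support it: these arrays differed from those of ewes 1 to 4 in 4767 features before any extra zinc, and the same ewes in 268 at day 40. Zinc supplementation cannot be told apart from it: the blocked difference between arms exceeded its relabellings, 74 against at most 5, and the changes of the 2 sets of ewes, all given extra zinc, correlated at r = 0.155.

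That division of the day 0 zinc arrays, made by their number of empty cells, was not matched by another of 100 splits into 4 and 6 arrays (1 of 100, 4618 features against at most 979, with the day 40 arrays as 1 group). The sets also lie apart on the second principal component at day 0. The zinc arm's change differed between the 2 sets of ewes in 731 features. Ewes 1 to 4 alone had 262 features changed over time, or 217 with the block, and ewes 5 to 10 alone had 3248, or 6823. Against the control arm, the change differed in 18 features for ewes 1 to 4 and 538 for ewes 5 to 10, or 0 and 2471 with the block. The sets hold 4 and 6 ewes, so these counts also differ in precision. The sets are samples sorted from these same arrays and not groups of the study, so the rank of their split gives no independent support. Whether a shared hybridization or the animals' state set them apart was not tested.

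For the level difference between the arms at day 40, the deposited count of 510 exceeded all other splits (1 of 100, highest other 47), while 10 were called on the common scale, 6 of them among the 510, as the median of all features went from -0.13 to 0.0587. Of the 510, 496 were lower in the zinc arm, while 0 calls were lower on the common scale and 0 with each array's median set equal. Those falls thus went with the offset between the arms. With zinc ewes 5 to 10 alone the day 40 count on the common scale was 368, 362 higher and 6 lower, mostly in the direction opposite to the 496. With all zinc ewes, the median of 0.0587 on that scale lay in the direction of these rises. With all zinc ewes and features with values on all arrays, quantile normalized together, 0 features were called at day 40. Whether the rises go with the scale was not tested. Whether separate normalization of the arms was the source stays open, as this was seen before it was tested. At day 0 the deposited count of 4748 also exceeded all other splits (1 of 100, highest other 734), and the 956 features on the common scale exceeded their own highest other split, 81, which argues against separate normalization as the whole cause. The day 0 arrays of ewes 5 to 10 may add to it: on the common scale 4 of them differed from the control ewes in 2456 features at the median of 15 draws, against 699 for ewes 1 to 4, with all 10 zinc arrays of day 40 kept in these fits. A difference between the animals before treatment stays open and untested.

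On the absence of calls in the control arm, draws of 5 of the 10 zinc ewes gave 0 calls in 1 of 100, with a median of 71 and a highest of 2964. All 10 zinc ewes gave 1607, so fewer ewes lowered the count strongly. For a change like that of the zinc arm, the draws argue, but only weakly, against the smaller number of ewes as the whole cause of 0 calls. Each draw held some of ewes 5 to 10, whose changes correlated with each other at a median of 0.48, unlike 5 unrelated ewes. The control count itself ran from 0 to 22 when 1 array was left out. A smaller change could be missed. Of features with a simulated log2 change of 0.5, 26.9% were called in the control arm and 52.2% in the zinc arm. Every split reaches a real count of 0 (100 of 100), so splits decide nothing about chance there; the highest other count was 10 for the control arm and 28 for the difference in time change. With the block, the real 2 control calls were matched by 1 other of the 16 sets of swapped days (2 of 16, highest other 2). Sets of that number cannot give a share under 0.05.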

How the results depend on the processing

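Features with values on all arrays, the common scale, the running median, array class, the number of empty cells, sets of zinc ewes and leaving out a ewe from the blocked fits were chosen after the data were examined. The cause of a change was not tested unless stated. With the ewe as a block the counts were 4457 in the zinc arm, 2 in the control arm and 74 for the difference in time change. With the ewe as a random effect they were 6239, 51 and 638, and the counts between arms stayed within 1.5 times. Standard errors of the random effect fit are approximate for features with a gap. Limma's quantile normalization gave 13338 and 3 features for the zinc and control changes, 3707 at day 40, 352 at day 0 and 1931 for the difference, because it ranks only the cells that hold a value and arrays lacking more dim features are lowered. With each array's median set equal, the day 40 count was 2 and the day 0 count 1225, since this removes the offset between arms. Without the dimmest 25% of features the day 40 count was 914. Without the dimmest 50% it was 1807, with 1 feature for the difference in time change. Array weights gave 2518 in the zinc arm, 1124 at day 40 and 35 for the difference. A minimum of 1.5-fold left 429, 49 and 1327 features in the zinc arm, at day 40 and at day 0, by construction. A fit to the compared groups alone gave 1013 in the zinc arm and 18 at day 40. A variance trend with robust estimation moved no count by over 1.5 times. The correlation of time changes, 0.0947, was 0.224 without the dimmest 50% and 0.011 under limma's quantile normalization. It was 0.161 on features with values on all arrays, 0.0476 on the common scale and 0.156 with both. Gene list tests, including those with mean probes, an estimated correlation, the block or quantile normalization, were not run because features have no gene names.

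On features with values on all arrays, the day 40 count was 1163 and the difference 12. On the common scale the counts were 10 at day 40, 956 at day 0 and 20 for the difference. With both choices together they were 0 at day 40 and 1140 at day 0. With the running median along the feature numbers removed they were 1 at day 40 and 1139 at day 0. With array class as a block on features with values on all arrays, they were 245 at day 40 and 179 for the difference, or 0, 3111 at day 0 and 185 after quantile normalization together. Fits with array class rest on ewes 5 to 10 for the zinc arm at day 0. With the number of empty cells as a covariate the counts were 3975 in the zinc arm, 2407 at day 40 and 1069 for the difference. Zinc ewes 1 to 4 alone gave 262, 37 and 18 for the zinc arm, day 40 and the difference, and on the common scale 239, 47, 583 at day 0 and 17, with the other zinc ewes left out on both days. Zinc ewes 5 to 10 alone gave 3248, 1109 (257 higher, 852 lower) and 538, and on the common scale 3716, 368 (362 higher, 6 lower) and 576, so the direction at day 40 turned with the scale. In the blocked fits, features with values on all arrays gave 1 control call and 200 for the difference, and after quantile normalization together 1 and 202. The common scale and the running median each gave 1 control call. With the block, ewes 1 to 4 alone gave 217 in the zinc arm and 0 for the difference, and ewes 5 to 10 alone 6823 and 2471.

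Leaving out 1 array gave 1057 to 1952 features in the zinc arm, 0 to 22 in the control arm, 7 to 1000 at day 40, 3533 to 4975 at day 0 and 0 to 30 for the difference, and a correlation of 0.0589 to 0.115. The zinc arm's count moved by over 1.5 times without the day 0 array of ewe 9 (1057) or the day 40 array of ewe 10 (1068). The day 40 count did so without the zinc arrays of ewes 1 (262), 5 (873), 6 (334), 7 (208), 8 (263), 9 (335) and 10 (56), or the control arrays of ewes 1 (7), 3 (30), 4 (12) and 5 (1000). The control arm's 0 became 8, 1, 2 and 22 without the day 0 arrays of ewes 1, 2, 4 and 5, and 1 and 2 without the day 40 arrays of ewes 3 and 4. The difference reached 30 without the day 0 control array of ewe 5, 21 without the day 40 control array of ewe 4, and at most 4 without any other array. Leaving out 1 ewe from the blocked fits gave 2555 to 5261, 1 to 4 and 1 to 163 features. The blocked zinc count moved by over 1.5 times without ewes 6 (2967), 7 (2833), 9 (2555) and 10 (2636). The blocked difference did so without zinc ewes 1 (163), 2 (20), 3 (40), 6 (20), 7 (22), 8 (41), 9 (20) and 10 (12), and control ewes 1 (12), 2 (1), 3 (9) and 5 (18).

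No named feature changed direction under the settings that gave it a value. The features were picked for the largest called changes on these same arrays, and 20 settings for each only left out 1 array, so a reversal was unlikely. Feature 19829 kept its call in all 31, with adjusted p-values from 0.000219 to 0.0256. Of 32 settings each, the call was lost in 1 for feature 11678, with zinc ewes 1 to 4 alone (log2 change 1.14, against 2.01 in ewes 5 to 10), and in 2 for feature 41820, with either set of zinc ewes alone (-2.14 in ewes 1 to 4 and -1.04 in ewes 5 to 10). It was lost in 7 for feature 36109, with either set alone (-2.47 and -0.95) and without each of 5 arrays. Adjusted p-values reached 0.139, 0.0806 and 0.391. Under limma's quantile normalization features 11678 and 19829 rose by 0.94 and 1.23, against 1.68 and 1.76 in the main fit. Features 36109 and 41820 changed by -2.32 and -2.00, against -1.61 and -1.46, and each kept its call. Dim features limit the precision: the median residual SD was 0.557 on the log2 scale in the dimmest 25% and 0.21 in the brightest.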

Other observations

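The tests here were chosen after the data were examined. Neighbouring feature numbers moved together at the ends of the numbering. The 295 tested features among the first 500 numbers had a median change of -0.263 in the zinc arm and 0.0648 in the control arm. The 298 among the last 500 had -0.156 and 0.0166, and the 34216 between had 0.0204 and 0.0109. Empty cells made up 34% of the first 500, 35.2% of the last 500 and 17% of the rest. These end features held 2 and 3 of the rises and 14 and 16 of the falls called in the zinc arm. Changes of adjacent numbers correlated at r = 0.0827 in the zinc arm and 0.0689 in the control arm, across features.

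Single ewes of a set resembled each other in their change. Each change takes off the day 0 array by which the sets were sorted, so likeness within a set partly restates that sorting. The median correlation across 22526 features between changes of 2 ewes was 0.48 within ewes 5 to 10, 0.273 within ewes 1 to 4, 0.0927 between these sets and 0.103 within the control arm. Between zinc and control ewes it was 0.0358 for ewes 5 to 10 and 0.0544 for ewes 1 to 4, both below the value between the sets of zinc ewes.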
